A study of Solea solea with 71 samples.

How the data were processed

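Liver RNA of 71 juvenile common sole (Solea solea, a flatfish) was measured on Agilent arrays, 1 fish per array and 1 dye (Cy3). Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.1.1, and the deposited scanner files hold the intensity of every spot on a linear scale. The intensity used here is the processed signal, from which the scanner software had already removed the background. A deposited table of the whole series holds the authors' own processed intensity for the same 71 arrays. Its columns lay on a linear scale and followed the scanner values of their arrays (r of 0.998 to 1.000 across probes after log2). The medians of the columns ran from 90.6 to 172.6, but 22.1% of the probe values were blank, in unequal shares. Over the 6499 probes with no blank the medians lay between 394.7 and 427.4, where those of the scanner signal ran from 217.7 to 656.7, so the columns lay near a common level. The method that set it is not given in the sources used here, and the values were used without further scaling.

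Each array carried 15237 features, of which 536 were controls and 14701 were probes of 60 bases. The files give each probe only an identifier of its sequence contig or read. None of the 14701 probes had a gene name or description other than that identifier, and 0 identifiers matched the gene table of the species' reference assembly (37145 genes). Probes are therefore reported by identifier, with no gene name and no position in a genome. The pathway and cell type gene lists fixed before the data were examined could not be matched to probes, and no list was tested.

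The log2 processed signal of each array was reduced by the 75th percentile of its 14701 probes. The scanner's outlier flags removed 309 spots. A probe was tested if it was well above background, by the scanner's flag, on at least 50% of the arrays of at least 1 group, which left 10675 probes. Means of the 4 groups were fitted with limma 3.58.1 (R 4.3.3) with a moderated two-sided test and Benjamini-Hochberg adjustment, and a probe was called changed at an adjusted p under 0.05. All 7 comparisons came from this fit. The hypoxia effect averaged over the 2 diets, the diet effect averaged over the 2 oxygen conditions, the interaction was the difference between the hypoxia effects of the diets, and the simple effects compared 2 groups each. For probes without a gene name, the rule fixed in advance allowed at most 2 that rose and 2 that fell, and did not say how to choose them. Those printed here had the 2 largest rises and the 2 largest falls per comparison among those called. Because they were chosen by size in these same fish, their changes tend to be overstated. For the interaction, where no probe was called, the 2 smallest p-values in each direction were used. The values of groups are means of log2 signal relative to the 75th percentile of the array, with the SD between fish.

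The fit was tested on simulated data drawn from the real probe means and spreads over 10675 probes. For the hypoxia effect it recovered 58 of 100 probes changed by 0.5 on the log2 scale and 94 of 100 changed by 1. For the interaction it recovered 26 of 100 and 66 of 100. False calls made up 5.59% of all calls for the hypoxia effect and 8% for the interaction. The simulated noise was independent between probes and held no batches, so these rates need not hold for the real arrays.

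The arrays came from 13 slides and 6 scan days, which held the 4 groups unevenly. Scan day 4 held 8 arrays, all of normoxic fish, and day 5 held 9, of which only 1 was of a hypoxic fish. Oxygen condition and scan day are therefore partly confounded. Only 3 scan days, with 11, 18 and 17 arrays, held at least 2 fish of all 4 groups. Alternatives fixed in advance covered the background correction (normexp with an offset of 50), the scaling, the filter on dim probes, the slide and the scan day as blocks, array weights, exclusion of arrays by their correlation with their group, the spread model, the groups in the fit, the deposited table and a fold threshold of 1.5. The offset of 50 is added to every signal, so normexp by itself shrinks the log2 changes of dim probes. Added after the data were seen were normexp followed by quantile normalization, a covariate for a block of co-varying probes, removal of each array's GC trend and leaving out each array in turn. The block was found by average-linkage clustering of all probes with an SD between fish of the same group above 1.5, joined at a mean correlation of 0.7. Other splits of the fish were drawn 99 times beside the real one, and again, after the data were seen, within scan days and within slides; the reshuffles for the interaction were repeated in the same way. Tests of a single value per fish used 100000 permutations. The number of arrays limits the precision of each value.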

Results

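The series asked how the lipid content of the juvenile diet affects the response of the sole liver to severe hypoxia. Fish of 8 months were fed for 2 months on a diet with 11% or 20% lipids. For the hypoxia groups, 19 fish of each diet were pooled in a single tank and left unfed for 48 h. The oxygen level was then lowered from 100% to 10% within 1 h and further by 2% per h to 4%, and each fish was sampled when it lost its equilibrium. Another 18 fish of each diet were sampled in normoxia; the labels do not say whether these were also unfed. The arrays comprised 18 normoxic fish on 11% lipids, 18 normoxic fish on 20% lipids, 16 hypoxic fish on 11% lipids and 19 hypoxic fish on 20% lipids. Only 16 of the 19 hypoxic fish on 11% lipids thus have arrays, and the labels do not say why. Because all hypoxic fish shared 1 tank, the hypoxia effect includes any effect of that tank. If the normoxic fish were fed, the hypoxia effect also includes any effect of the 48 h without food.

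Between 9135 and 11414 of the 14701 probes were well above background on an array (median 10309). The 75th percentile of the processed signal ranged from 196.2 to 586.7 intensity units, with medians of 373.3, 381.1, 340.1 and 368.7 in the normoxic 11%, normoxic 20%, hypoxic 11% and hypoxic 20% lipid groups. The highest correlation between any 2 arrays was 0.976, and no array duplicated another. The first principal component held 12.5% of the variance. A block of 99 probes rose and fell together between fish, and its mean log2 signal ranged from -6.57 to 2.12. The block mean was -5.0 ± 1.80 (SD, n = 18) in normoxic fish on 11% lipids, -4.50 ± 2.23 (n = 18) in normoxic fish on 20% lipids, -3.45 ± 3.26 (n = 16) in hypoxic fish on 11% lipids and -4.73 ± 1.86 (n = 19) in hypoxic fish on 20% lipids. The 4 groups did not differ in it beyond the spread between fish (permutation test, p = 0.243, adjusted p = 0.370 over 6 tests of the block mean).

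Hypoxia changed 960 of the 10675 tested probes over both diets, of which 369 were higher and 591 lower in hypoxic fish. Without the 7 arrays that correlated least with their own group, 451 were higher and 440 lower. The median change of the called probes was 1.29-fold, and 59 changed at least 2-fold, 17 upward and 42 downward. The probe P_isotig07186 (sequence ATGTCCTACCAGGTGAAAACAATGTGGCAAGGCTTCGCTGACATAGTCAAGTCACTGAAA) fell by 2.23 ± 0.33 (SE) on the log2 scale, a 4.71-fold change (limma adjusted p = 2.03e-06). Its signal was 3.57 ± 1.77 (SD, n = 18) and 3.06 ± 1.47 (n = 18) in normoxic fish on 11% and 20% lipids, against 0.91 ± 1.05 (n = 16) and 1.26 ± 1.30 (n = 19) in hypoxic fish, and 34 of 35 hypoxic fish lay below the median of the normoxic fish on their diet. N_isotig08992 showed the largest fall, by 2.38 ± 0.51 or 5.20-fold (adjusted p = 0.000993, lower in 28 of 35 fish). N_isotig15646 (sequence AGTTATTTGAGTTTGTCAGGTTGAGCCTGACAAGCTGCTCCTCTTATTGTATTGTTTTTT) rose by 1.29 ± 0.24, or 2.45-fold (adjusted p = 8.89e-05), and was above the normoxic median in 32 of 35 fish. The largest rise, of 1.54 ± 0.52 for P_isotig11036, lay close to the threshold (adjusted p = 0.0459) and lost the call under 8 of 14 alternatives and in 42 of the 71 fits that left out 1 fish. With the slide as a fixed block 421 probes were called, and with normexp background correction 560. With the scan day as a block 846 were called, but these held only 597 of the 960. With scan day 1, 2 or 3 left out, the probes called on the other days had the same sign within that day in 83.7% of 717, 66.3% of 945 and 95.3% of 384 cases. Within day 1 alone 0 probes passed, within day 2 there were 2, both lower, and within day 3 there were 3 higher and 22 lower.

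**Figure D1:**
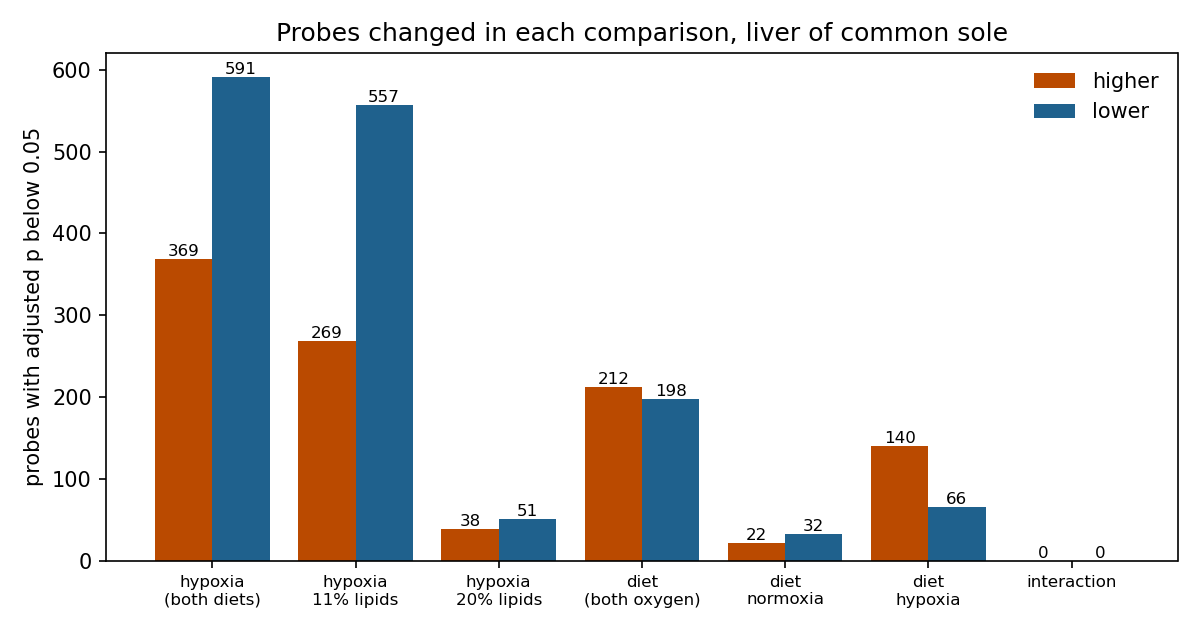
Number of probes (y axis) with an adjusted p under 0.05 in each of the 7 comparisons (x axis), with higher probes in orange and lower probes in blue. Hypoxia changed 269 probes upward and 557 downward in fish fed 11% lipids, against 38 and 51 in fish fed 20% lipids, and no probe passed for the interaction.

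In fish fed 11% lipids, hypoxia changed 826 probes, 269 upward and 557 downward, 103 of them at least 2-fold. N_isotig17357 (sequence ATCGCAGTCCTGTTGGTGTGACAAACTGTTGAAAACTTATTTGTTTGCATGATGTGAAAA) fell by 3.30 ± 0.46, or 9.82-fold (adjusted p = 7.11e-07), from 1.91 ± 1.15 (SD, n = 18) to -1.39 ± 1.36 (n = 16), and all 16 hypoxic fish lay below the normoxic median. It was not well above background on 1 of those 16 arrays. N_isotig08992 fell by 3.44 ± 0.74 (adjusted p = 0.00186, 15 of 16 fish). N_isotig06751 rose by 1.78 ± 0.38, or 3.43-fold (adjusted p = 0.00169, 15 of 16 fish). P_isotig07685 rose by 2.16 ± 0.59 (adjusted p = 0.0151, 15 of 16 fish) and belongs to the block of 99 co-varying probes; it was the only block member among the 826. It lost the call with normexp and without the 7 arrays of low correlation (adjusted p up to 0.192), 5 of which were hypoxic fish on 11% lipids. With the scan day as a block 910 probes were called, but these held only 616 of the 826. With the block mean as a covariate, chosen after the data were seen, 624 probes were called. Without those 7 arrays 463 were called, 222 upward and 241 downward, and normexp background correction left 210.

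In fish fed 20% lipids, 89 probes changed, 38 upward and 51 downward, 21 of them at least 2-fold. N_isotig03616 fell by 1.47 ± 0.29, or 2.77-fold (adjusted p = 0.0019), from 1.97 ± 1.02 (SD, n = 18) to 0.50 ± 0.78 (n = 19), with 18 of 19 fish below the normoxic median. P_isotig07186 fell by 1.81 ± 0.46 (adjusted p = 0.0312, 18 of 19 fish), a call lost with the slide as a fixed block (adjusted p = 0.0581) and in 8 of the 71 fits that left out 1 fish. P_G6W9YEI01C0SLX rose by 1.11 ± 0.24, or 2.17-fold (adjusted p = 0.00621, 17 of 19 fish), and N_G6W9YEI02IPCIT by 1.21 ± 0.31 (adjusted p = 0.0328, 15 of 19 fish). Neither passed with the slide as a fixed block or with normexp, and the second also lost the call with the scan day as a block, in the deposited table and in 12 of those 71 fits. Under the alternatives the rise went down to 0.22 for P_G6W9YEI01C0SLX and to 0.35 for N_G6W9YEI02IPCIT. The count was 15 with the slide as a fixed block and 378 with normexp (192 upward, 186 downward), which under this scaling moved the median of all tested probes by -0.15 on the log2 scale.

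The 2 hypoxia effects share no fish. However, the hypoxic fish of both diets shared 1 tank, and scan days 4 and 5 held almost only normoxic fish of both diets. Any effect of the tank or the scan day would therefore add to the agreement between the 2 hypoxia effects. Across the 10675 probes, which are not independent replicates, they correlated at r = 0.25 (0.14 with normexp, 0.38 over the probes well above background on every array). Random error in each estimate pulls this r toward 0, so it does not measure how alike the true effects were. Splits of the oxygen labels within diets gave a median r of 0.021 and a highest of 0.403, and splits of the diet labels within oxygen conditions a median of 0.420 and a lowest of 0.124, with 4 of 100 as low as the real one. Of the 826 probes called in fish fed 11% lipids, 78.6% had the same sign in fish fed 20% lipids, and their median change there, in the same direction, was 0.14 against 0.51 on the log2 scale. Of the 89 called in fish fed 20% lipids, 96.6% had the same sign in fish fed 11% lipids. Their median change there, in the same direction, was 0.48 against 0.59 on 20% lipids. Each list was chosen by the p-values of its own diet, so the changes in that diet tend to be overstated. The 50 probes called in both diets had the same direction in each case, 18 upward and 32 downward, where independent lists would share 0.958 and 2.66.

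**Figure D2:**
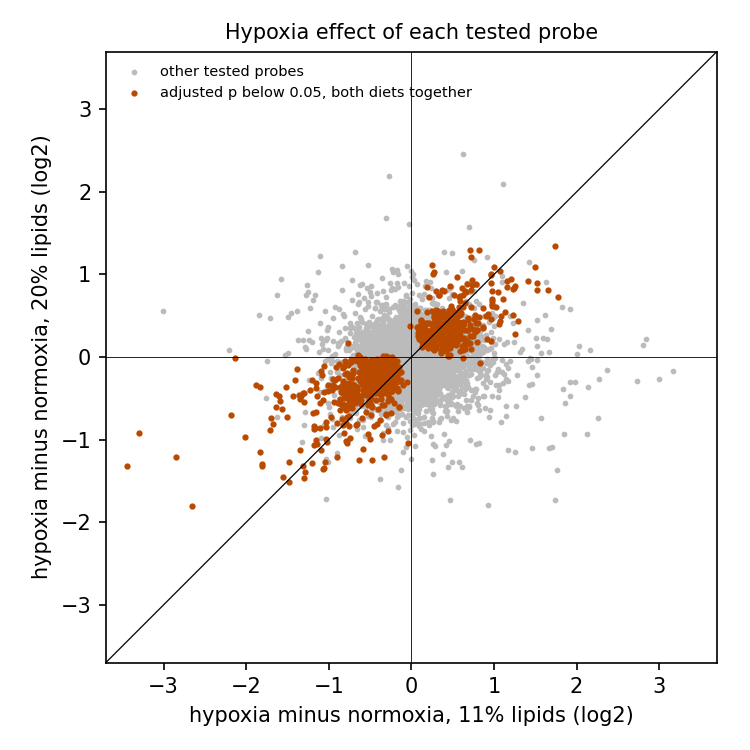
Each point is 1 of the 10675 tested probes, with its log2 difference between hypoxia and normoxia in fish fed 11% lipids (x axis) and 20% lipids (y axis); probes called for hypoxia over both diets are orange and the line marks equal effects. The estimated effects correlated at r = 0.25, a value that error in the estimates pulls toward 0. The largest falls lay further from 0 on the x axis.

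Whether the response to hypoxia depended on the diet was tested by the interaction, and limma called 0 probes (smallest adjusted p = 0.109), with 1148 at an unadjusted p under 0.05. Normexp called 5 probes, array weights 4 and the scan day as a block 1. The smallest p belonged to N_isotig06252, whose interaction was 0.94 ± 0.20 (p = 1.13e-05, adjusted p = 0.109). Its signal was 0.17 ± 0.33 (SD, n = 18) in normoxia and -0.60 ± 0.41 (n = 16) in hypoxia on 11% lipids, against -0.01 ± 0.46 (n = 18) and 0.16 ± 0.46 (n = 19) on 20% lipids. For AS_isotig05670 the value was 0.43 ± 0.09 (p = 2.23e-05). Both passed with normexp and with array weights (smallest adjusted p = 0.026 for each), and the first also with the scan day as a block. The smallest p-values below 0 belonged to P_G6W9YEI02HPIPO, at -3.47 ± 0.85 (p = 0.000125) with signal well above background in only 9 of 18, 16 of 18, 13 of 16 and 9 of 19 fish of the normoxic 11%, normoxic 20%, hypoxic 11% and hypoxic 20% groups, and to P_isotig03916, at -1.32 ± 0.33 (p = 0.000152), which passed with normexp (adjusted p = 0.0397). Under 14 alternatives the interaction of P_G6W9YEI02HPIPO ran from -3.65 to -0.745. N_isotig17357, which fell in hypoxia on 11% lipids, had an interaction of 2.37 ± 0.63 (adjusted p = 0.164).

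The diet changed 410 probes over both oxygen conditions, 212 higher and 198 lower in fish fed 20% lipids, 11 of them at least 2-fold. P_isotig15568 (sequence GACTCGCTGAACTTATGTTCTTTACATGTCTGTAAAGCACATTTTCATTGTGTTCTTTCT) was 7.02-fold higher in fish fed 20% lipids (2.81 ± 0.24 on the log2 scale, adjusted p = 3.8e-14). Its signal was 3.68 ± 0.80 (SD, n = 18) and 4.48 ± 1.07 (n = 16) in normoxic and hypoxic fish on 11% lipids, against 6.82 ± 0.72 (n = 18) and 6.96 ± 1.37 (n = 19) on 20% lipids, and 36 of 37 fish on 20% lipids lay above the median of their oxygen condition on 11% lipids. N_isotig09387 rose by 1.54 ± 0.44 (adjusted p = 0.0309, 29 of 37 fish), but not past the threshold with the slide as a fixed block or in the deposited table (adjusted p up to 0.112); it was well above background in 15 of 18 normoxic and 11 of 16 hypoxic fish on 11% lipids. N_isotig06704 fell by 3.69 ± 1.06 (adjusted p = 0.0329, 29 of 37 fish), with SDs between 2.52 and 5.12 and signal well above background in 14 of 18, 12 of 18, 16 of 16 and 14 of 19 fish of the normoxic 11%, normoxic 20%, hypoxic 11% and hypoxic 20% groups. It lost the call under the same 2 settings (adjusted p up to 0.262). N_isotig13264 fell by 1.67 ± 0.50 (adjusted p = 0.0381, 29 of 37 fish) and lost the call under 7 of 14 alternatives and in 18 of the 71 fits that left out 1 fish. It was well above background in 15 of 18, 11 of 18, 15 of 16 and 13 of 19 fish of the groups in that order, and with the values on 20% lipids raised to at least the lowest signal well above background on each array its 3.19-fold change became 2.19-fold. The count was 204 with the slide as a fixed block, 544 with the scan day as a block, 145 with normexp and 810 without the 7 arrays of low correlation (302 higher, 508 lower). With scan day 1, 2 or 3 left out, 85.3% of 320, 100% of 58 and 91.3% of 265 called probes had the same sign within that day, while no probe passed within any one of these days.

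**Figure D3:**
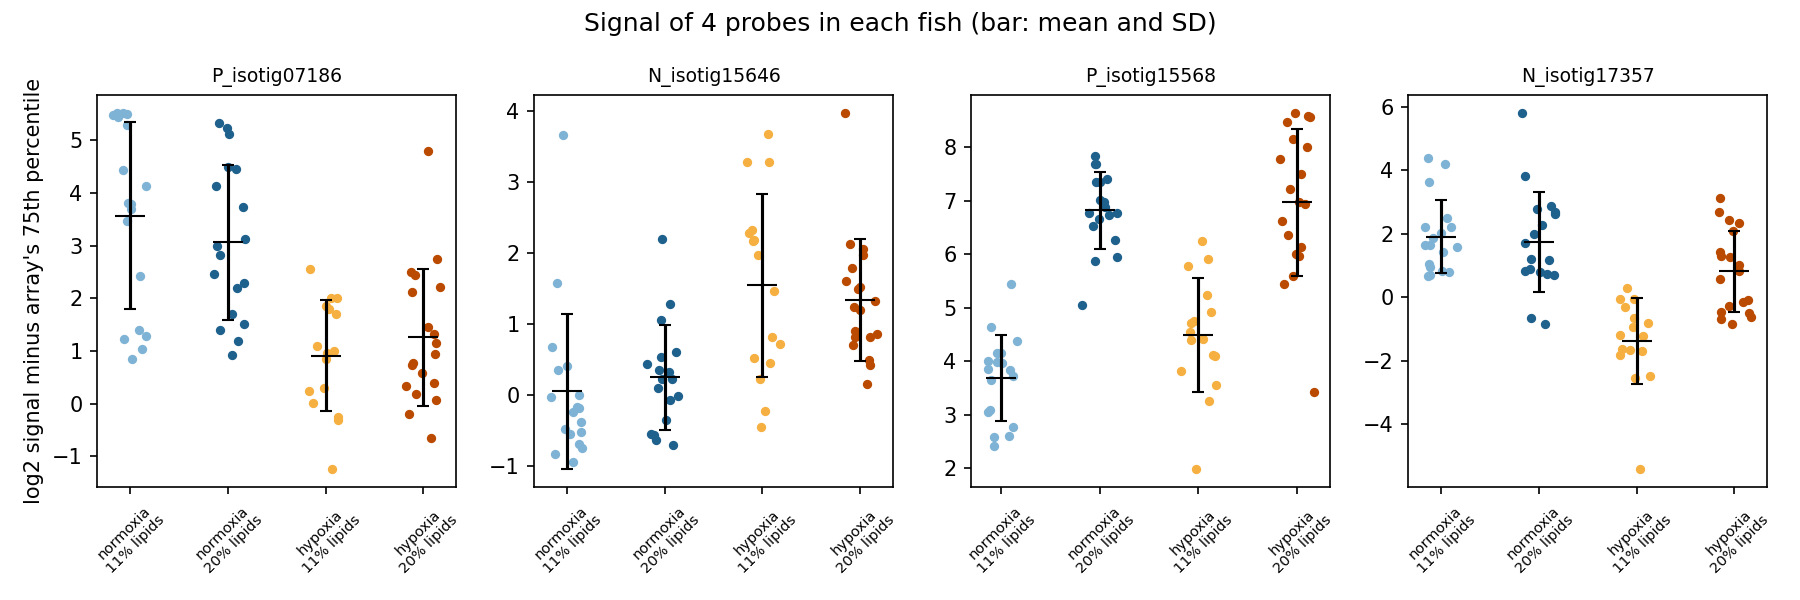
Log2 signal relative to the 75th percentile of the array (y axis) of 4 probes in each fish of the 4 groups (x axis), with the mean and SD in black. P_isotig07186 was lower and N_isotig15646 higher in hypoxia, P_isotig15568 was higher on 20% lipids, and N_isotig17357 was lowest in hypoxic fish on 11% lipids, at -1.39 ± 1.36 (SD, n = 16).

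In normoxia the diets differed in 54 probes, 22 higher and 32 lower on 20% lipids. P_isotig15568 was 8.81-fold higher (adjusted p = 6.65e-10, 18 of 18 fish) and N_G6W9YEI02GNM6W 1.94-fold higher (adjusted p = 0.0471, 18 of 18 fish). The latter was well above background in only 10 of 18 fish on 11% lipids, and it lost the call under 8 of 14 alternatives (difference down to 0.20 on the log2 scale) and in 29 of the 71 fits that left out 1 fish. P_isotig17953 was 2.36-fold lower (adjusted p = 0.038, 16 of 18 fish), a call lost with the slide as a fixed block, without the filter on dim probes (adjusted p up to 0.137) and in 15 of those 71 fits. P_G6W9YEI02FIOVR was lower by -1.70 ± 0.38 (adjusted p = 0.0195, 18 of 18 fish) but was well above background in only 13 of 18 and 5 of 18 fish, and its difference was 0.02 with normexp. Its 3.24-fold difference became 1.92-fold with the values on 20% lipids raised to at least the lowest signal well above background on each array, and it also lost the call with the slide as a fixed block. The count fell to 16 with the slide as a fixed block and to 25 without the filter on dim probes, and rose to 113 with the scan day as a block and to 223 with array weights. Leaving out 1 fish moved it from 21, without normoxic 20% lipid fish 97, to 83, without normoxic 11% lipid fish 70. The direction of the majority turned with quantile normalization (47 higher, 33 lower), in the deposited table (36 and 30) and with the slide block (9 and 7).

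In hypoxia the diets differed in 206 probes, 140 higher and 66 lower on 20% lipids. P_isotig15568 was 5.60-fold higher (adjusted p = 4.32e-06, 18 of 19 fish) and N_isotig17357 4.59-fold higher (adjusted p = 0.00377, 19 of 19 fish). N_isotig07204 fell by 1.47 ± 0.29 (adjusted p = 0.00237, 19 of 19 fish) and P_isotig10862 fell by 1.33 ± 0.33 (adjusted p = 0.0215, 18 of 19 fish). The latter lost the call with normexp, the slide as a fixed block, array weights and without the 7 arrays of low correlation (adjusted p up to 0.148). The split by direction turned round without those 7 arrays, to 108 higher and 154 lower, and was 99 higher and 96 lower in the deposited table and 111 and 93 with the block mean as a covariate. Normexp called 27 probes, a fit to only these 2 groups called 76, and 136 were called without hypoxic 11% lipid fish 36. The hypoxia and diet effects correlated at r = -0.23 across probes, where splits of the oxygen labels gave a median of -0.04 and a lowest value of -0.24. Both effects come from the same fish. With the hypoxia effect taken from about 50% of the fish of each group, drawn at random, and the diet effect from the rest, in 100 such draws made after the data were seen, r had a median of -0.13 and ran from -0.38 to 0.08. The covariance had a median of -0.00987 in these draws, against -0.0129 over all fish.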

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

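The test of the block covariate was set before its result was seen, and the comparisons of the 2 diets came from the design; the bounds for normexp with each scaling, the measures of spread of the effects and the splits and reshuffles within scan days and slides were chosen after the counts had been seen. More probes changed with hypoxia in fish fed 11% lipids (826) than in fish fed 20% lipids (89), and the difference of 737 was tested by reshuffling the diet labels within each oxygen condition. Only the real split of 100 gave a difference as large (1 of 100, highest other 590). With 99 other splits, 1 of 100 is the smallest share possible. The real split was also the only one as large within scan days (highest other 399) and within slides (highest other 373). Reshuffling the diet labels removes every effect of the diet, so these splits alone do not show that the 2 hypoxia responses were unequal. With the main settings and all arrays, the SD of the hypoxia effects after removal of the error was 0.28 in fish fed 11% lipids. In fish fed 20% lipids it was 0.16, both on the log2 scale. This difference in variance was reached by 2 of 100 splits of the diet labels, which carry the same limit. The SDs were not computed with normexp or without the arrays of low correlation, so their dependence on these settings was not tested. For the interaction no single probe passed, and 1148 probes had an unadjusted p under 0.05, against at most 1059 in the other 99 reshuffles of the fish around the additive fit (1 of 100). Those reshuffles ignored the batches; within scan days and within slides 3 of 100 gave as many (highest others 1390 and 1650), so chance reshuffles did reach such a count. With the scan day or the slide as a fixed block the count was 1353 and 1370.

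For this difference between the diets, the tables argue against the block of co-varying probes and the fish that carry it as the whole cause, since the count in fish fed 11% lipids stayed 6 times that in fish fed 20% lipids with the block mean as a covariate (624 against 104; 9.28 times without it). The ratio was smaller without the 7 arrays of low correlation (463 against 138), so a part may come from those fish. However, 5 of the 7 were among the 16 hypoxic fish on 11% lipids, so their loss also lowers the power of that comparison. Normexp with 75th percentile scaling turned the order round (210 against 378), while quantile normalization gave 854 against 115 without normexp and 798 against 115 with it, a ratio of 6.94. No other setting turned the order. The counts were 749 against 85 in the deposited table and 721 against 15 with the slide as a fixed block. With the scan day as a block they were 910 against 81. The order turned only when normexp and 75th percentile scaling were combined, which moved the median of all tested probes by -0.15 for hypoxia on 20% lipids. Neither step is singled out, and how far the size of the difference rests on the processing stays open. A biological difference between the diets in the size of the response also stays open, as a hypothesis. Each hypoxic fish was sampled at its own loss of equilibrium, so time and oxygen level at sampling may have differed between the diets. Neither was compared, so unequal exposure cannot be told apart from the diet.

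Other splits of the fish ignored slide and scan day. None reached the real counts for hypoxia (960, highest other 1) or diet in normoxia (54, highest other 1). Nor did any for hypoxia on 11% lipids (826, highest other 240) or 20% lipids (89, highest other 4). Each of these is 1 of 100 splits as large, the smallest share possible here. For diet (410, highest other 585; 2 of 100) and diet in hypoxia (206, highest other 256; 2 of 100), 1 other split gave more calls than the real one, so chance splits reached such counts, though in under 5 of 100. Of the 99 other splits, counting the one with 585 calls itself, 2 were at least as uneven over scan days as that one and 20 at least as uneven over slides. On the first and the second principal component, 9 and 7 were at least as far apart. That split was thus more uneven over scan days than most, but whether this gave its calls was not tested. With the scan day as a block the diet count was 544. With labels reshuffled only among fish of 1 scan day, the highest others were 207 for hypoxia, 289 and 46 for hypoxia on 11% and 20% lipids and 1 for each of the 3 diet counts. Within slides they were 723 for hypoxia, 794 and 57 for hypoxia on 11% and 20% lipids, and 4, 9 and 6 for diet, diet in normoxia and diet in hypoxia. None of these splits reached the real counts, but those within slides changed the oxygen label of a median of only 16 fish, and with the slide as a fixed block 15 probes were called for hypoxia on 20% lipids and 16 for diet in normoxia.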

How the results depend on the processing

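Normexp with quantile normalization, the block covariate, the GC correction and leaving out single arrays were chosen after the data were seen. No paired analysis was possible because groups share no fish numbers. Gene list tests were not run, since no probe had a gene name.

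The causes of the changes were not tested. Quantile normalization after normexp brought all counts but that for diet in normoxia within 1.5 times the main ones. With normexp the counts were 560 for hypoxia, 145 for diet (54 higher, 91 lower), 5 for the interaction, 210 and 378 for hypoxia on 11% and 20% lipids, 106 for diet in normoxia (22 higher, 84 lower) and 27 for diet in hypoxia, and the correlation was 0.14; this setting moved the median of all tested probes by 0.11 for diet in normoxia and by -0.15 for hypoxia on 20% lipids. The slide as a fixed block gave 421, 204, 15 and 16 for hypoxia, diet, hypoxia on 20% lipids and diet in normoxia. The scan day as a block gave 1 for the interaction and 113 for diet in normoxia. Array weights gave 649 for diet, 4 for the interaction, 168 for hypoxia on 20% lipids and 223 for diet in normoxia. Without the 7 arrays of low correlation, counts were 810 for diet, 463 and 138 for hypoxia on 11% and 20% lipids and 132 for diet in normoxia. For diet in normoxia, no filter gave 25, normexp with quantile normalization 111 and the 2 groups alone 123; for diet in hypoxia the 2 groups alone gave 76. A fold of at least 1.5 left 209, 78, 333, 45, 26 and 93 probes for hypoxia, diet, hypoxia on 11% and 20% lipids and diet in normoxia and hypoxia. Over probes well above background on every array the correlation was 0.38. The share of higher probes also moved without the 7 arrays (451 of 891 for hypoxia, 302 of 810 for diet, 222 of 463 for hypoxia on 11% lipids, 108 of 262 for diet in hypoxia), with quantile normalization (331 of 528 for diet, 47 of 80 for diet in normoxia; 332 of 521 and 64 of 111 after normexp), in the deposited table (36 of 66 for diet in normoxia, 99 of 195 for diet in hypoxia) and with the block covariate (111 of 204 for diet in hypoxia).

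Leaving out 1 array at a time gave 827 to 1075 probes for hypoxia, 355 to 498 for diet, 0 to 2 for the interaction, 641 to 941 and 71 to 115 for hypoxia on 11% and 20% lipids, 21 to 83 for diet in normoxia, 136 to 257 for diet in hypoxia and a correlation of 0.20 to 0.30. Diet in normoxia fell to 21, 28, 31, 32 and 34 without normoxic 20% lipid fish 97, 69, 91, 71 and 81, to 25, 26, 29 and 32 without normoxic 11% lipid fish 74, 94, 64 and 92, and rose to 83 without fish 70. The interaction reached 2 without hypoxic 11% lipid fish 28 and 1 without hypoxic fish 2 or 35 or normoxic fish 81 or 83. Of the 24 called probe results, 12 kept their call under all settings that kept every array or dropped the 7; P_G6W9YEI02FIOVR alone turned sign, to 0.021 for diet in normoxia with normexp.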

Other observations

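The tests of the slide and of the slopes within the block, and that of the ATTTA motif, were chosen after the values had been seen. The removal of the GC trend was also added after the data were seen, but its bounds were set before its own result. A block of 99 probes, 52 of them among the tested probes, rose and fell together between fish (block mean from -6.57 to 2.12), and 7 further blocks of at least 5 probes were found. The 4 highest block means, from 1.37 to 2.12, belonged to hypoxic fish on 11% lipids, 4 of the 7 fish whose arrays correlated least with their group. A slide effect is argued against, because the block mean spanned over 4 log2 units on 8 of the 13 slides. Whether RNA of another tissue or cell type in unequal amounts gave the block stays open. Such an admixture needs slopes near 1 between probes, and 60.8% of 4847 pairs had a slope between 0.8 and its reciprocal where both were above background, against 96.2%, 82.9%, 41.8%, 42.9%, 86.7%, 70% and 20% in the other 7 blocks. This decides nothing, because probes entered a block by an SD above 1.5 and a mean correlation of 0.7, which favours such slopes, and without gene names neither a tissue nor a process can be tested.

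The hypoxia t statistic rose weakly with the GC content of the probe (r = 0.076 across probes), and 21 of 100 splits of the oxygen labels gave an r as high. A GC trend of single arrays as the origin of the calls is argued against, since 90.9% of the 960 hypoxia calls kept an adjusted p under 0.05 after each array's trend was removed. It was also asked, as a hypothesis, whether the 915 tested probes with the motif ATTTA, part of AU-rich elements that control mRNA decay, rose more than others of like GC content. Their mean t was higher by 0.075, which 2 of 100 splits reached (highest other 0.076). A linear model of the t on GC content and the motif across probes, run first, gave a like coefficient of 0.074 ± 0.062 (SE) that did not pass (p = 0.236). Reshuffling the oxygen labels removes every hypoxia effect, so those splits cannot tell the motif from any other set of probes that changed. The linear model treats the probes as independent. Neither test decides the question, and the difference is small, so whether the motif matters stays open.

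On the array, 174 contigs had a probe of each orientation. Both probes were well above background on over 50% of the arrays for 56 contigs, only one of them for 41 and 41, and neither for 36. Hypoxia changed 6 of 103 tested probes of the first orientation and 10 of 104 of the second, against 487 of 5240 and 457 of 5228 in the other 2 classes of probe. The mean distance of a fish from the mean profile of its group was 0.66, 0.66, 0.72 and 0.69 log2 units in the normoxic 11%, normoxic 20%, hypoxic 11% and hypoxic 20% lipid groups, and the groups did not differ in it beyond the spread between fish (permutation test, p = 0.0647).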
